A study of Homo sapiens with 6 samples.

How the data were processed

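The series profiled microRNAs (miRNAs) in HK-2, an established cell line of human kidney proximal tubular epithelium. Per the labels, cells were grown in 10% fetal calf serum, moved to 0.2% serum and kept for 48 h with or without 5 µg/ml aristolochic acid. There were 3 samples per group and 1 array per sample. Per the labels' protocols, total RNA was extracted with TRI-Reagent, and 500 ng was labelled with a mercury LNA microRNA labelling kit in 1 colour (Cy5). The scanner, the slide layout and the software behind the files are not given in the sources used here. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

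Each deposited array file lists 3136 spots with a raw intensity, a background-subtracted intensity, an average, a globally normalized intensity and a flag, per the file headers. Of these spots, 1719 were human miRNA probes, with 1 spot each, and 1248 were blank. The steps behind the authors' columns were worked out from the values and are stated in no source used here. The background equals the mean of the blank spots after trimming 5% at each end. A background-subtracted intensity is given only where the raw intensity exceeds that mean by 2 SDs of the trimmed blanks, and such spots are called detected here. The authors' globally normalized intensity multiplies each array by 1 factor that brings the median of its detected probes to 25. The authors' deposited value table holds the same normalized intensities for all 1719 probes, with a largest difference of 4.1e-05. Its scale is linear and not centred.

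The raw intensities were the starting point. Background was corrected with normexp and an offset of 50, with the trimmed blank mean as background. Values were log2 transformed and quantile normalized over the 1719 miRNA probes. Spots with a bad flag were left out, and these were 1 miRNA spot on control replicate 1 and 1 on aristolochic acid replicate 1. A probe was tested if detected on at least 3 of the 6 arrays, which left 784 probes. Of all probes, 503 were detected on every array and 497 on none. Groups were compared with limma (lmFit and eBayes), and adjusted p-values follow Benjamini-Hochberg with a threshold of 0.05. Every log2 fold change is on the scale of signal plus 50, so it understates the change of dim probes. The authors' normalized intensities are therefore given beside it as mean ± SD (n = 3, for probes detected on all 6 arrays). Those intensities are not on the scale of the fit: over the 503 probes detected on every array, the median difference between treated and control arrays was -0.21 on the log2 scale of the authors' values and -0.01 after quantile normalization. No gene coordinates are given, because the files name no genome build. The gene table of assembly GRCh38.p14 was used only for which miRNA genes lie near each other.

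Before the data were examined, the groups, tests, alternatives and 19 miRNA lists were fixed. The lists hold miRNAs linked to p53, epithelial identity, fibrosis, inflammation, kidney tubules and hypoxia, the miR-15/16, miR-29, let-7, miR-17-92, miR-23/27/24 and miR-221/222 families, fragments of other RNAs, and markers of endothelium, mesenchyme and smooth muscle, striated muscle, blood, neural tissue and liver. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry. The miRNAs named are those past the threshold up to 10 per direction, then those of lowest unadjusted p up to 10 per direction, 10 fixed miRNAs, and up to 4 members of lowest p per list. Single values per array were compared by an exact two-sided permutation test, whose smallest p with 3 against 3 arrays is 0.1.

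The fit was tested on simulated data that carried known changes over 767 probes. It recovered 17.5% of 57 probes changed 1.5-fold, 32.1% of 56 changed 2-fold and 65.0% of 60 changed 4-fold, and of its 77 calls 67 were these recovered probes, 9 were unchanged probes and 1 belonged to a simulated list given a smaller shared shift. Alternatives covered the background correction, the normalization, the detection filter, the deposited value table, the variance model, array weights, replicate number as a block, and leaving out each array. After the data were seen, an offset of 16, scaling by the spike controls and linear scaling before the offset were added. Versions were R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.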

Results

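MiRNA levels were measured in HK-2 proximal tubular cells after 48 h with 5 µg/ml aristolochic acid (n = 3 arrays) and in untreated control cells (n = 3 arrays). Aristolochic acid is a plant compound that damages the proximal tubule and forms DNA adducts. The number of arrays limits the precision of every value. Detected probes numbered 879, 936 and 644 on control replicates 1 to 3 and 647, 873 and 739 on aristolochic acid replicates 1 to 3, out of 1719 miRNA probes.

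The series' design asks which miRNAs differed between treated and control cells. After aristolochic acid, miR-4730 rose by 1.01 ± 0.08 (SE) on the log2 scale, from a normalized intensity of 288 ± 84.7 to 658 ± 93.9 (SD, n = 3; limma adjusted p = 0.00299). MiR-450a, encoded in a cluster with miR-424, miR-503 and miR-542, rose by 0.55 ± 0.05, from 23.4 ± 3.54 to 91.1 ± 24.9 (adjusted p = 0.00299). MiR-194, abundant in kidney and intestinal epithelium and encoded next to miR-192, rose by 0.35 ± 0.05, from 38.5 ± 7.73 to 80.0 ± 15.6 (adjusted p = 0.0183). MiR-205, an epithelial miRNA that represses the transcription factors ZEB1 and ZEB2, fell by 0.32 ± 0.04 on the log2 scale, from 258 ± 64.1 to 148 ± 21.8 (adjusted p = 0.0183). Its raw intensity was 130.1 ± 8.37 in control and 130.6 ± 8.33 in treated cells (SD, n = 3). These raw values include background, and the blank spots were at 51.1 in control and 57.7 in treated arrays. Without normalization its log2 fold change was -0.04 (limma adjusted p = 0.507), so its fall was mostly relative to the other probes.

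MiR-3663-3p and miR-3135b were the other called miRNAs. MiR-3663-3p rose by 0.51 ± 0.05 on the log2 scale, from 240 ± 68.5 to 351 ± 52.9 (adjusted p = 0.00299). MiR-3135b rose by 0.69 ± 0.10, from 174 ± 54.0 to 335 ± 109 (adjusted p = 0.0232). In all, 6 of 784 tested probes passed the threshold, 5 higher and 1 lower in treated cells. For each of these 6, all 3 treated arrays lay on the same side of all 3 control arrays. Such separation was seen for 124 tested probes (15.8%), where chance gives 10%. At an unadjusted p under 0.05 there were 99 probes, 46 higher and 53 lower, where 39.2 are expected by chance. The other splits of the same arrays into 3 and 3 mix the groups, and they gave from 18 to 59 such probes. They keep part of any group difference, so this range is not the spread expected without one.

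Several miRNAs next in rank did not pass. The higher ones included miR-192 and miR-200c, whose values are given below. The others were miR-542-3p, which shares the miR-450a cluster (log2 fold change 0.29 ± 0.05, adjusted p = 0.0717), miR-1228* (0.22 ± 0.04, adjusted p = 0.0717) and miR-1290 (0.41 ± 0.08, adjusted p = 0.0798). The lower ones were miR-106a (-0.33 ± 0.06, adjusted p = 0.0611), miR-140-3p (-0.18 ± 0.04, adjusted p = 0.0885), miR-30a* (-0.17 ± 0.03, adjusted p = 0.0885), miR-33a (-0.17 ± 0.04, adjusted p = 0.125) and, with the same adjusted p, miR-664 (-0.19), miR-3197 (-0.19), miR-3647-3p (-0.19), miR-92a (-0.15) and miR-4657 (-0.14). MiR-542-3p, miR-1228* and miR-1290 passed with median scaling (log2 fold changes 0.36, 0.55 and 0.72, adjusted p = 0.0128, 0.00298 and 0.000549), where all 81 calls were higher, and in 8, 6 and 6 of 20 alternatives. MiR-106a passed as lower without the detection filter (adjusted p = 0.0377) and with scaling to the 75th percentile (0.0472). MiR-140-3p, miR-33a, miR-664, miR-3647-3p and miR-4657 passed as lower with that scaling, where 353 of 398 calls were lower. Without normalization, miR-30a* and miR-3197 passed as higher.

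**Figure D1:**
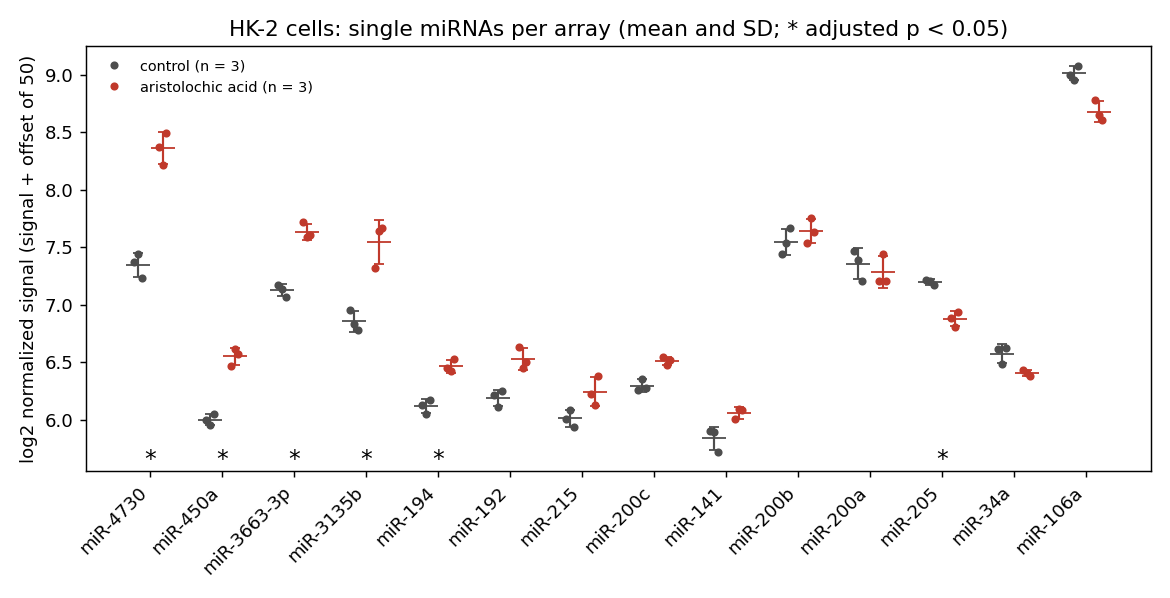
Log2 normalized signal (signal plus an offset of 50) of 14 miRNAs on each array, with control arrays in grey and aristolochic acid arrays in red. Points are single arrays, bars are the mean and SD of 3 arrays, and an asterisk marks the 6 miRNAs with an adjusted p under 0.05, of which miR-205 lies lower in treated cells and the other 5 lie higher.

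MiR-4730, miR-450a and miR-3663-3p passed in each of the 6 fits that left out an array (adjusted p from 0.00609 to 0.0291), while miR-194 passed only without control replicate 3 (adjusted p = 0.0460, and 0.0591 to 0.0905 without each other array), miR-205 only without aristolochic acid replicate 3 (0.0309, and 0.0591 to 0.0969) and miR-3135b only without replicate 1 of control (0.0333) or of aristolochic acid (0.00609, and 0.0962 to 0.153 otherwise). Plain background subtraction left 0 calls in limma, with 70 probes at an unadjusted p under 0.05, and the deposited value table left 1 (miR-450a). MiR-205 was also lost with median scaling (log2 fold change -0.12, adjusted p = 0.241), no normalization (-0.04, 0.507), spike control scaling (-0.16) and replicate number as a block (adjusted p = 0.132), and miR-3135b with that block (adjusted p = 0.132). The split of the calls followed the scaling: it was 81 higher and 0 lower with median scaling, 306 and 0 with no normalization between arrays, 45 and 353 with scaling to the 75th percentile, and 52 and 0 with spike control scaling.

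Among the 10 miRNAs fixed in advance, miR-194 and miR-205 passed and 8 did not. MiR-192, which is encoded beside miR-194 and is abundant in the renal tubule, had a log2 fold change of 0.34 ± 0.06 (SE), with normalized intensities of 47.2 ± 10.1 in control and 87.2 ± 4.89 in treated cells (SD, n = 3; adjusted p = 0.0717). All 3 treated arrays lay above all 3 control arrays for miR-192 (exact permutation p = 0.1, the smallest the design allows). MiR-215, which shares the seed sequence of miR-192, had a log2 fold change of 0.23 ± 0.07 (adjusted p = 0.237). MiR-34a, a direct transcriptional target of p53, lay in the other direction at -0.17 ± 0.05, with 111 ± 24.1 in control and 71.7 ± 12.4 in treated cells (adjusted p = 0.200), except with no normalization between arrays, where its log2 fold change was 0.04. It passed as lower only with scaling to the 75th percentile (-0.21, limma adjusted p = 0.0206), where 353 of 398 calls were lower.

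Within the miR-200 family, which represses ZEB1 and ZEB2, miR-200c had a log2 fold change of 0.22 ± 0.04 (adjusted p = 0.0717) and its cluster partner miR-141 one of 0.22 ± 0.06 (adjusted p = 0.157). MiR-200b was at 0.09 ± 0.07 (adjusted p = 0.711) and miR-200a at -0.07 ± 0.09 (adjusted p = 0.788). With median scaling, miR-200c (0.36, adjusted p = 0.00408), miR-141 (0.25, 0.0295) and miR-200b (0.44, 0.00629) passed, and they did so in 5 of 20, 4 of 18 and 4 of 20 alternatives. With median scaling the median change of the tested probes was 0.045 and all 81 calls were higher, so these passes include that shift. With scaling to the 75th percentile, where that median was -0.13, miR-200c (0.18, adjusted p = 0.0204) and miR-200b (0.26, 0.0208) passed as higher and miR-141 did not pass. MiR-21, an abundant miRNA linked to renal fibrosis, was at 0.71 ± 0.53 (adjusted p = 0.688). Its raw intensity was 1364 on control replicate 3 and between 8229 and 13759 on the other 5 arrays. By brightness it ranked 5 on control replicate 3 and 2 on each other array, so without control replicate 3 quantile normalization gave it a log2 fold change of 0. MiR-192 passed the threshold without the detection filter (adjusted p = 0.0478), with a variance trend and robust fit (0.00673), with median scaling (0.00858), with scaling to the 75th percentile (0.0185), without normalization (0.00253), and, among settings added later, with an offset of 16 (0.0307), spike control scaling (0.0285) and linear scaling before the offset (0.0398). It was also among the 9 miRNAs called with array weights. It did not pass with plain background subtraction (log2 fold change 1.06, adjusted p = 0.231) or in the deposited value table (0.90, adjusted p = 0.552).

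The fixed lists asked whether miRNAs of related function or origin moved together. The miR-17-92 family and its paralogs, which are linked to proliferation, fell as a group relative to the other probes (camera adjusted p = 0.0116, and adjusted p = 0.390 with an estimated correlation), except with median scaling, scaling to the 75th percentile or no normalization, where the group lay 0.04 above them. In treated cells, 11 of 13 measured members were lower, and the mean log2 fold change less that of the other probes was -0.14. No member passed over all probes, and 2, miR-106a and miR-92a, passed adjusted over the list alone. MiR-106a was at 1283 ± 228 in control and 839 ± 120 in treated cells and miR-17 at 1053 ± 143 and 766 ± 221 (normalized intensity, SD, n = 3). Fry, which tests the family against no change and not against other probes, gave an adjusted p of 0.146. The camera call was lost without control replicate 3 (adjusted p = 0.130) or aristolochic acid replicate 2 (adjusted p = 0.0564). It was also lost with plain background subtraction (difference from other probes -0.15, adjusted p = 0.328), the deposited value table (-0.20, 0.273) and the trend and robust fit (-0.14, 0.0856), where the difference was no smaller, and with spike control scaling, where it was -0.04 (0.276).

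The other 14 lists tested did not pass after quantile normalization. In the epithelial list, 5 of 7 members were higher and 2 lower (adjusted p = 0.271). Of these, miR-205 passed over all probes as lower, and 3 higher members (miR-200c, miR-141 and miR-203) and miR-205 passed adjusted over the list alone, and the list passed as higher with scaling to the 75th percentile (adjusted p = 0.0258). In the kidney tubule list, 6 of 11 were higher and 5 lower (adjusted p = 0.271), with miR-194 called over all probes and miR-192 with it adjusted over the list alone. Its other 9 members, among them miR-30a (-0.07 ± 0.04) and miR-196a (0.05 ± 0.04), passed neither. This list passed as higher than the other probes, by 0.20, with median scaling (adjusted p = 0.000403), scaling to the 75th percentile (2.36e-05) and no normalization (0.00386). In the p53-responsive list, 3 of 12 members were higher and 9 lower (adjusted p = 0.908). The 3 higher ones were miR-192, miR-194 and miR-215, which passed adjusted over the list alone, as did miR-34a on the lower side, and only miR-194 passed over all probes. The list's mean and median were below 0, while fry gave an upward direction.

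**Figure D2:**
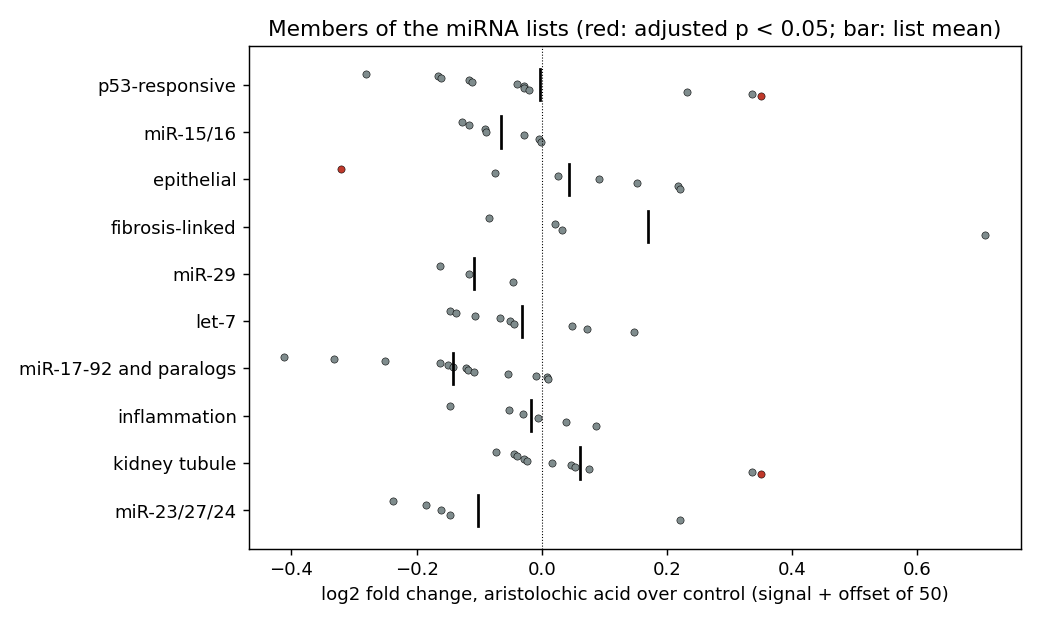
Log2 fold change (aristolochic acid over control, on the scale of signal plus 50) of each tested member of 10 fixed miRNA lists. Each point is 1 miRNA, red points have an adjusted p under 0.05 (miR-194, in 2 lists, and miR-205), and the bar is the list mean, which with quantile normalization lies lowest for the miR-17-92 family.

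The miR-15/16, miR-29, miR-23/27/24 and let-7 families did not pass after quantile normalization, where all 4 lay below the other probes, but lay above them with median scaling, scaling to the 75th percentile, no normalization or spike control scaling. With scaling to the 75th percentile the let-7 (adjusted p = 0.00405) and miR-23/27/24 (0.0258) families passed as higher. After quantile normalization, all 7 members of the miR-15/16 family were lower (adjusted p = 0.271), among them miR-424 (-0.09 ± 0.04) and miR-15b (-0.13 ± 0.07), as were all 3 of the collagen-repressing miR-29 family (adjusted p = 0.271), with miR-29c at -0.12 ± 0.05 and miR-29b at -0.16 ± 0.09. In the miR-23/27/24 family, 4 of 5 were lower (adjusted p = 0.271), and miR-27a (-0.19 ± 0.05) and miR-24 (-0.15 ± 0.05) passed adjusted over the list alone. The let-7 family had 3 of 9 higher (adjusted p = 0.868), with let-7c at -0.15 ± 0.11 and let-7g at 0.15 ± 0.11.

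The fibrosis-linked list had 3 of 4 tested members higher (adjusted p = 0.868), with miR-214 at -0.08 ± 0.04. The inflammation list had 2 of 6 higher (adjusted p = 0.868), with miR-155 at -0.15 ± 0.05 and miR-132 at 0.09 ± 0.05. Of the 4 tested miRNAs that can derive from fragments of other RNAs, 1 was higher (adjusted p = 0.823), with miR-1260 at -0.31 ± 0.13 and miR-1246 at 0.36 ± 0.17, and with scaling to the 75th percentile that list passed as higher (0.33, adjusted p = 0.0047). Markers of other cell types did not pass: mesenchyme and smooth muscle had 0 of 3 higher (adjusted p = 0.374), striated muscle 2 of 4 (0.827), blood 1 of 3 (0.998) and neural tissue 2 of 3 (0.868). The blood list's mean was above 0 and its median and fry direction were below. Lists with fewer than 3 tested members had no set test. The hypoxia-induced miR-210 was at -0.20 ± 0.06 (adjusted p = 0.240), miR-221 at 0.14 ± 0.08 (adjusted p = 0.541), miR-222 at -0.01 ± 0.08 (0.969), the endothelial miR-126 at -0.01 ± 0.04 (0.898) and the hepatic miR-122 at 0.06 ± 0.05 (0.693).

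Overall signal differed between the groups. The median raw intensity of miRNA probes was 53.4 ± 1.13 in control and 60.9 ± 3.57 in treated arrays (SD, n = 3; exact permutation p = 0.1, the smallest the design allows), and the blank spots were at 51.1 ± 0.648 and 57.7 ± 4.22 (exact permutation p = 0.1). After background subtraction, the median of the 503 probes detected on every array was 15.4 ± 1.02 in control and 22.1 ± 1.14 in treated arrays, a ratio of 1.44 (exact permutation p = 0.1). The number of detected probes was 820 ± 155 and 753 ± 114 (exact permutation p = 0.6), a difference within the spread between arrays that went from -66.7 to -8.5 without control replicate 2 and to -154.5 without control replicate 3. The authors' scaling factor was 3.23 ± 0.520 and 2.04 ± 0.364 (exact permutation p = 0.1).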

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

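The tests on chance for the number of miRNAs, on overall array brightness, on brighter background, on brighter miRNA signal and on miR-21*, and the linear scaling before the offset, were chosen after the data were seen. Control spots, which enter no comparison of miRNAs, were brighter on every treated array than on every control array for 4 kinds of spot. The ratio of treated to control means was 1.13 for blank spots, 1.13 for negative control spots, 1.13 for QC probes and 1.12 for S probes (exact permutation p = 0.1 each, the smallest the design allows). Spike controls had a ratio of 1.14 with overlapping groups (exact permutation p = 0.2).

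The pattern of 6 called miRNAs, 5 of them higher, was weighed against that brighter background, in which the blank spots of a treated array exceeded the control mean by at most 10.7. For each of the 5 higher miRNAs, the lowest treated array lay at least 25.9 above the highest control array in raw intensity, which argues against added background as the whole source of these 5. MiR-205 stayed lower (-0.33 ± 0.05 (SE), and -0.32 ± 0.04 with each array's own background) when the mean control background was subtracted from every array before linear scaling. This cannot decide whether a brighter background was the source there. Raw miR-205 was alike in both groups (130.1 and 130.6). Linear scaling divides by probes detected on every array, of which 99.2% were higher on treated arrays without normalization, so it lowers miR-205 with either background. Brighter miRNA signal on the treated arrays is argued against as the whole source of the 5 higher calls, which were all kept with cyclic loess and with scaling to the 75th percentile, where the median change of the tested probes went from 0.12 without normalization to -0.0043 and -0.13, but stays open for miR-205, whose call was kept under 2 of 4 scalings (cyclic loess and linear scaling) and lost under median scaling (-0.12) and spike control scaling (-0.16). Among the 10 splits of the arrays into 3 and 3, only the real one gave as many as 6 calls and the highest other gave 1, but 10 splits cannot reach a share under 0.05, and an effect of the treatment and any difference in handling stay open.

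The lower miR-17-92 family was weighed against probe brightness, since 12 of its 13 members lie above the upper quartile of brightness among the tested probes. Of 10000 random lists matched on brightness, a share of 0.0005 had a mean as low as the family's -0.14 (their median was 0.01 and their central 95% ran from -0.08 to 0.13). Probes of that brightness were thus not lower in general, which argues against brightness alone. The draws treat probes as independent and leave out correlation between members and the spread between arrays, so the share is no p-value for the family. Camera with an estimated correlation (adjusted p = 0.390) and fry (0.146) did not pass. The estimated correlation was 0.0059, below the preset 0.01, so a higher correlation between members is not what removed the camera call. Without normalization the family lay 0.04 above the other probes, and it lay there by the same amount with median scaling. The equal values decide nothing, because 1 factor per array on log values cannot change a list's distance from the other probes. Linear scaling before the offset put the family below other probes (-0.137, camera adjusted p = 0.00319). That was the result predicted if scaling after the offset was behind the higher position, so this explanation stays open. Spike control scaling, also applied before the offset, put the family below other probes by less (-0.037, camera adjusted p = 0.276). Why these settings differ was not tested. For the count of lists, 3 of the 10 splits gave as many as the real 1, and the highest other split gave 1; so few splits cannot reach a share under 0.05. Relatedness of probe sequences within the family was not tested, and an effect of the treatment stays open.

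The low miR-21 on control replicate 3, at 0.145 of the other control arrays after background subtraction, sets the wide error of that miRNA. A dim array is argued against by the 25 brightest other probes, whose median ratio was 0.832 (lowest 0.562). A mislabelled sample is argued against by the 25 miRNAs of lowest p in a fit without that array, on which it lay at a median position of 0.164 between the means of the other controls (0) and the treated arrays (1), with 7 of 25 above 0.5. Less miR-21 transcript is argued against by miR-21*, the other arm of the hairpin, at a ratio of 0.847, although that probe is dim (raw 64.2 over blanks of 50.6). A defect of the single spot stays open, and no biological explanation was tested.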

How the results depend on the processing

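An offset of 16, spike control scaling and linear scaling before the offset were chosen after the data were seen. So was the measure of a list's direction, its mean less that of other probes, in place of camera's direction. The 6 called miRNAs kept their direction under all 20 alternatives tried for them. Their calls did not all hold. MiR-450a passed under all but plain subtraction. MiR-4730, miR-3663-3p, miR-194, miR-205 and miR-3135b were lost with plain subtraction (log2 fold changes 1.35, 0.76, 1.25, -0.56 and 1.11). They were also lost with the deposited value table (1.23, 0.59, 1.05, -0.77 and 0.94). Each of these values was larger in size than in the fit on signal plus the offset. Plain subtraction and the deposited values carry no offset, so these sizes are not on the scale of that fit. MiR-205 was lost in 11 of the 20, also with median scaling (-0.12), no normalization (-0.04), spike control scaling (-0.16) and the replicate block, and miR-3135b also with that block. With 1 array left out, miR-205 and miR-194 passed in 1 of 6 fits each and miR-3135b in 2. Signal over background was low, with the median of the probes detected on every array 15.4 above the blanks in control arrays.

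The count of called miRNAs, 6, went to 0 with plain background subtraction (70 at an unadjusted p under 0.05), 81 with median scaling, 398 with scaling to the 75th percentile, 306 without normalization, 1 with the deposited value table, 52 with spike control scaling and 16 with linear scaling before the offset, and ranged from 3 to 5 when 1 array was left out, with 3 without aristolochic acid replicate 2. The median change of the tested probes was 0.12 without normalization, 0.045 with median scaling and 0.075 with spike control scaling. It was -0.13 with scaling to the 75th percentile and -0.21 in the deposited values. Calls under these settings include that shift. The count of lists past the threshold, 1, went to 0 with plain subtraction, the deposited value table, a variance trend in camera and an estimated correlation. It also went to 0 with spike control scaling and with fry (a test against no change). With scaling to the 75th percentile it went to 5 (kidney tubule, let-7, fragment-derived, miR-23/27/24 and epithelial, all higher). It ranged from 0 to 1 when 1 array was left out. With median scaling and without normalization the count was 1 but the list was the kidney tubule list, higher, and not the miR-17-92 family (adjusted p = 0.626 and 0.751). The log2 fold change of miR-192, 0.34, passed the threshold at 0.46 with median scaling, 0.28 with the 75th percentile, 0.53 without normalization, 0.34 without the detection filter, 0.34 with trend and robust fit, 0.58 with an offset of 16, 0.46 with spike control scaling and 0.37 with linear scaling before the offset, was also called with array weights, and did not pass at 1.06 with plain subtraction or 0.90 in the deposited values. It ranged from 0.28 to 0.38 when 1 array was left out. The cause was not tested. The median raw intensity stayed higher in treated arrays and the number of detected probes lower under every alternative tried for them, but the difference in detected probes, -66.7, was -37.0 without control replicate 1, -8.5 without control replicate 2, -154.5 without control replicate 3, -13.7 without aristolochic acid replicate 1 and -126.7 without aristolochic acid replicate 2.

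Replicate numbers did not pair the samples: the deviations of same-numbered arrays correlated at -0.13, -0.18 and 0.0032. With replicate number as a block (replicate block), 4 miRNAs and 1 list passed, and miR-192 was at 0.34 (adjusted p = 0.126).

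Of 47 followed miRNAs that did not pass, 30 passed in the same direction under at least 1 alternative, most often miR-192 and miR-542-3p (8 of 20 each), miR-1228* and miR-1290 (6 each), miR-200c (5), miR-200b and miR-141 (4 each) and miR-215, miR-203 and miR-221 (3 each). In the other direction 10 passed, all of them without normalization except miR-450b-5p, which did so with scaling to the 75th percentile. The fit with array weights, which is outside these counts, also called miR-106a, miR-192 and miR-542-3p.

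Of 53 miRNAs and 15 lists followed (miRNAs by log2 fold change, lists by their mean less that of other probes), the following changed sign, none of them a called miRNA, and the cause was not tested. With median scaling these were miR-30a* 0.11, miR-3197 0.13, miR-92a 0.071, miR-200a 0.18, let-7c 0.16, miR-126 0.025, miR-1260 0.17, miR-155 0.016, miR-15b 0.17, miR-17 0.079, miR-222 0.30, miR-24 0.18, miR-27a 0.22, miR-29b 0.14, miR-29c 0.14, miR-30a 0.22, miR-424 0.29 and miR-503 0.033. With scaling to the 75th percentile they were miR-200a 0.0037, miR-122 -0.11, miR-132 -0.081, miR-196a -0.020, miR-222 0.12, miR-24 0.0048, miR-27a 0.047, miR-30a 0.042, miR-424 0.11, miR-450b-5p -0.12 and miR-542-5p -0.10. Without normalization they were miR-106a 0.055, miR-140-3p 0.035, miR-30a* 0.19, miR-3647-3p 0.029, miR-4657 0.030, miR-3197 0.20, miR-92a 0.15, miR-664 0.034, miR-34a 0.045, miR-200a 0.25, let-7c 0.24, miR-126 0.099, miR-1260 0.25, miR-155 0.090, miR-15b 0.25, miR-17 0.15, miR-194* 0.064, miR-21* 0.067, miR-210 0.016, miR-214 0.036, miR-222 0.37, miR-24 0.26, miR-27a 0.30, miR-29b 0.22, miR-29c 0.22, miR-30a 0.29, miR-424 0.36 and miR-503 0.11. Under each of these 3 settings, which differ by 1 factor per array on log values and so move lists alike, they were also the p53-responsive list 0.053, miR-15/16 family 0.048, miR-29 family 0.10, let-7 family 0.19, miR-17-92 family 0.041, miR-23/27/24 family 0.16, neural markers -0.038 and fragment-derived list 0.33. With spike control scaling they were miR-30a* 0.059, miR-3197 0.071, miR-92a 0.027, miR-200a 0.13, let-7c 0.077, miR-126 0.056, miR-1260 0.069, miR-155 0.00035, miR-15b 0.11, miR-194* 0.034, miR-21* 0.0085, miR-222 0.25, miR-24 0.11, miR-27a 0.15, miR-29b 0.051, miR-29c 0.091, miR-30a 0.12, miR-424 0.21 and miR-503 0.066, and the p53-responsive list 0.032, miR-15/16 family 0.0038, miR-29 family 0.010, let-7 family 0.10, miR-23/27/24 family 0.068, neural markers -0.019 and fragment-derived list 0.21. With linear scaling before the offset they were miR-126 0.0057, miR-222 0.070, miR-424 0.0046 and miR-503 0.012, and the p53-responsive list 0.0021 and fragment-derived list 0.047. With cyclic loess it was miR-222 0.045. With plain subtraction they were the p53-responsive list 0.073, inflammation list 0.16 and blood markers -0.11. The neural markers -0.012 changed without the detection filter. Over probes detected on all arrays the p53-responsive list 0.0040 and epithelial list -0.012 changed, in the deposited values the p53-responsive list 0.15 and fragment-derived list 0.012, and with an offset of 16 the p53-responsive list 0.025 and blood markers -0.0013.

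Leaving out 1 array also turned the sign of miR-503 (-0.025 to 0.0083), miR-222 (-0.057 to 0.070), miR-126 (-0.042 to 0.0026), miR-194* (-0.039 to 0.0030), the p53-responsive list (-0.020 to 0.012), the inflammation list (-0.035 to 8.0e-05), the blood markers (-0.017 to 0.028), the neural markers (-0.0056 to 0.020) and the let-7 family (-0.070 to 0.012). Blocks for slide or scan were not run because the files used here give none. Probes of other species and the median over a probe's spots changed nothing, because all tested probes are human and have 1 spot each.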

Other observations

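Several neighbours and partner arms of the called miRNAs did not pass. MiR-424 and miR-503, encoded near miR-450a, had log2 fold changes of -0.09 (adjusted p = 0.400) and -0.0036 (0.976), miR-542-5p one of 0.05 (0.697) and miR-450b-5p one of 0.06 (0.553), beside 0.55 for miR-450a and 0.29 for miR-542-3p. MiR-194*, the other arm of a miR-194 hairpin, was at -0.02 (adjusted p = 0.854). These were chosen after their values were seen.

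A hypothesis drawn from the pairs miR-192 and miR-194, miR-200c and miR-141, and miR-450a and miR-542-3p was that miRNAs of neighbouring genes change together through shared transcription. Of 782 probes, 733 could be matched to a gene, and 210 pairs had genes within 10 kb of each other, leaving out pairs of the same number and keeping the pairs that prompted the test. Their log2 fold changes differed by a median of 0.07, as small as in a share of 0.318 of 10000 permutations within 5 classes of brightness, beside a permuted median of 0.0742. A share of 0.05 or more had been set in advance to count against the hypothesis, but that bound was wrong, because the difference lay on the side the hypothesis needs and a missed threshold excludes nothing. By a second measure, for which nothing was predicted in advance, 125 of the 210 pairs shared a direction against a permuted median of 105 (share as large 0.0082). That share was weighed after it was seen, and the 210 pairs are drawn from 151 miRNAs and are not independent. Many of the pairs that shared a direction involve members of the only fixed list that passed after quantile normalization. Most members of that list were lower, and its direction changed with the scaling. The count of pairs is thus not separate from that list's result. It was not tested without those pairs, so the hypothesis stays open.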
